A study of Homo sapiens with 12 samples.

How the data were processed

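The series measured transcript levels in MCF10A cells, a non-tumorigenic human breast epithelial line, with a stably expressed HER2 chimera, full length and tagged with FKBP and HA. Per the labels, cells received AP1510, TGF-alpha or heregulin, or were left untreated, and each of these 4 groups holds 3 arrays, 12 in all. AP1510 is a synthetic bivalent ligand of FKBP that brings tagged receptors together as homodimers. TGF-alpha is a ligand of EGFR, and heregulin is a ligand of HER3 and HER4. Per the labels' protocols, maintenance medium held 5% horse serum, 20 ng/ml EGF, 100 ng/ml cholera toxin, 500 ng/ml hydrocortisone and 10 microgram/ml insulin. Serum and EGF were withdrawn 24 hours before ligand while the other additions stayed, and RNA was taken 48 hours after ligand. The labels state that 100 mm dishes were seeded in triplicate, so p-values measure the spread between these dishes and their arrays. Dose, vehicle, batch and the harvest time of the untreated cells are not given in the sources used here, so a difference in time in culture between untreated and treated cells stays open for changes that the treatments share against untreated. The treated groups share the 48 hours, so it does not bear on contrasts between treatments.

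Per the labels, RNA was labelled with biotin and read on Affymetrix arrays. The deposited values are log2 intensities that the authors made with RMA, which corrects background, equalises the distributions of the arrays and summarises probes into probe sets. The version of RMA is not given in the submitters' processing notes. The unit was checked on the values, which ran from 1.75 to 14.2 with medians of 5.33 to 5.44 per array. No further scaling was applied. For arrays, their number limits the precision.

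The table held 33297 probe sets. Of these, 19460 named exactly 1 gene, 1754 named several and 12083 had no listed gene. Symbols were matched through Entrez IDs to RefSeq names for GRCh38.p14, which held 19429 of the probe sets with 1 gene. A gene was measured by the probe set with the highest mean over the 12 arrays, which mattered for 769 genes, and 18417 genes were tested. Probe sets with several genes or none were left out of the main test. A group of 4203 unlisted probe sets has IDs below the lowest listed one and was taken to hold the array's controls, an inference from the numbering alone. Control probe sets carry no names in the sources used here, so the planned comparison of 3' and 5' controls and of spike-ins was not analysed here.

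Genes were tested with limma 3.58.1 in R 4.3.3. All 12 arrays entered 1 linear model with a mean per group, which left 8 residual degrees of freedom, and the moderated spread had 7.55 prior degrees of freedom. The median moderated SD was 0.128 on the log2 scale. The 6 contrasts between groups were tested two-sided, p-values were adjusted by Benjamini-Hochberg over genes within each contrast, and the threshold was an adjusted p of 0.05. A moderated F test over the 3 contrasts against untreated asked which genes differed among the 4 groups. A gene was called apart in a treatment when its level lay above, or below, each of the other 3 groups in all 3 contrasts. Tested on simulated data for AP1510 against untreated alone, with 200 changed genes among 18417, the procedure recovered 91.5% of genes changed by 1.5-fold, 99.5% of those changed by 2-fold and 100% of those changed by 4-fold. It made 14, 4 and 15 false calls at these sizes, and 80.5% of genes changed by 1.5-fold were called apart. The simulated noise was drawn independently for each gene and array at the moderated SD, with no effect shared across a dish. These shares therefore do not tell how many real changes of such sizes were found.

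The 24 gene lists covered ErbB receptors and their ligands, ERK feedback and output genes, immediate early genes, DNA replication, mitosis, cell cycle arrest, FOXO targets, glycolysis, cholesterol synthesis, fatty acid synthesis, mesenchymal genes, epithelial junctions, basal and luminal mammary markers, squamous differentiation, extracellular proteases, inflammatory and NF-kB genes, interferon response, hypoxia, the amino acid and unfolded protein response, ribosome biogenesis, heat shock proteins, and leukocyte and endothelial markers. They held 486 listed genes, of which 450 were measured. Each list was tested in each contrast with limma's camera at a preset correlation between genes of 0.01, and the 144 tests were adjusted together. Of these, 72 passed at the preset correlation and 0 passed with a correlation estimated from the data, where the lowest adjusted p was 0.064 and 48 tests had an unadjusted p under 0.05. The self-contained test fry, which asks whether a list's genes move one way on balance, passed 100.

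The genes named in the text follow a rule. For each contrast against untreated, it takes the 12 largest rises and 12 largest falls among genes that passed and whose 3 treated arrays all lay on one side of the 3 untreated arrays. For each contrast between treatments it takes 10 per direction. It adds up to 4 members of each called list that changed in the list's direction, all members of the ErbB list, and for each treatment the 6 higher and 6 lower genes standing farthest apart. Not all genes that the rule takes are described. Further lists, on clock genes, acute phase genes, glucocorticoid-induced genes, metallothioneins, the epithelial sodium channel and histones, were chosen after values were seen and appear only in the closing section. Their camera p-values were adjusted among these later lists alone, over fewer tests than the planned lists. The adjusted p-values of later and planned lists are therefore not comparable. Similarity of responses was measured across genes by correlation, covariance and shared calls, beside 100 simulations of unchanged groups set against the same control arrays. Alternatives covered renewed quantile normalization, equal medians, removal of genes below the 40th percentile of mean level, a trended robust prior, array weights, each contrast on its own 6 arrays, all probe sets, the mean of probe sets, a 2-fold minimum, an adjusted p of 0.01, no moderation, and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.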

Results

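The data are 12 arrays of HER2-FKBP-HA MCF10A cells, 3 each from untreated cells and from cells given AP1510, TGF-alpha or heregulin for 48 hours. The harvest time of the untreated cells is not given in the sources used here. The design asks how transcription differs when ErbB receptors are engaged by forced HER2 homodimers, by an EGFR ligand or by a HER3 and HER4 ligand. Genes are named by symbol, each standing for a single probe set, such as 7996563 for HSD11B2, 8138289 for ETV1 and 8179351 for CFB. Errors beside log2 changes are standard errors from the fit, with n = 3 arrays per group. Arrays of the same group correlated at 0.988 to 0.994 and arrays of different groups at 0.978 to 0.993, across probe sets, which are not independent replicates. The first principal component held 48.6% of the variance and the second 19.6%. TGF-alpha arrays lay at 34.0 to 38.3 on PC1 and untreated arrays at -20.3 to -18.7. AP1510 replicate 1 lay at -2.43, nearer the TGF-alpha arrays than replicates 2 and 3 at -11.9 and -14.0. Heregulin arrays had the widest spread, with a median SD of 0.132 against 0.0963 to 0.107 in the other groups. Among the 4 groups, 5248 genes (28.5%) differed by the F test.

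**Figure D1:**
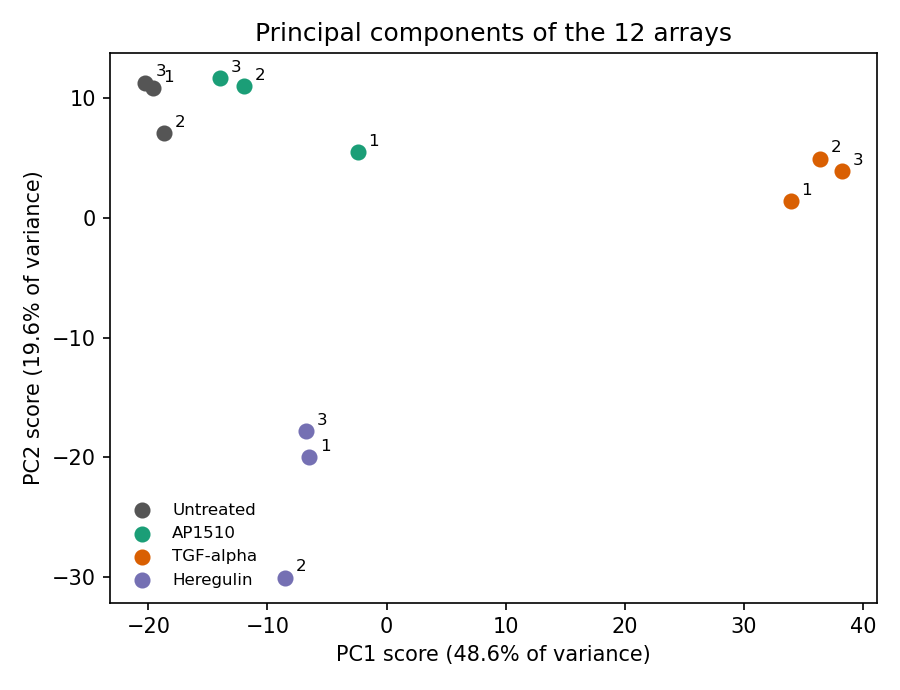
Scores of the 12 arrays on PC1 (48.6% of variance) and PC2 (19.6%), 1 point per array, coloured by group and numbered by replicate. TGF-alpha arrays separate along PC1 and heregulin arrays along PC2.

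The ErbB receptors themselves were measured on every array. ERBB2, which encodes HER2, stood at 10.9 ± 0.02 (SD, n = 3) in untreated cells, and its log2 change was -0.04 ± 0.08 with AP1510 (adjusted p = 0.94) and 0.01 ± 0.08 with heregulin (adjusted p = 0.95). The cells also express the full-length HER2 chimera, whose RNA the ERBB2 probe set may read together with that of their own gene. The values do not tell these apart, so a change in ERBB2 may come from either. With TGF-alpha, ERBB2 rose 1.46-fold (adjusted p = 8.2e-05), EGFR rose 1.27-fold (adjusted p = 0.0095) and ERBB3 fell 1.89-fold (adjusted p = 4.4e-06). With heregulin, EGFR rose 1.51-fold (adjusted p = 4.7e-04). HBEGF, which encodes an EGFR ligand, fell 3.75-fold with TGF-alpha (adjusted p = 2.2e-06) and 2.53-fold with heregulin (adjusted p = 3.8e-04). Its fall of 1.84-fold with AP1510 (adjusted p = 0.041) missed the threshold in 9 of the 12 refits that left out 1 array, with the highest adjusted p, 0.14, without untreated replicate 1. TGFA, which encodes TGF-alpha, rose 1.36-fold with TGF-alpha (adjusted p = 0.016) and 1.35-fold with heregulin (adjusted p = 0.047), and missed the threshold in 4 and 8 of these refits, at most without untreated replicate 2 (adjusted p = 0.084) and untreated replicate 3 (adjusted p = 0.18) respectively. Of the 11 measured list members, 1 fell with AP1510, 3 rose and 2 fell with TGF-alpha, and 2 rose and 1 fell with heregulin. Adjusted over the list alone, the counts were 2 fallen, then 3 risen and 3 fallen, then 2 risen and 1 fallen. Camera called the list in none of these 3 contrasts (adjusted p = 0.38, 0.89 and 0.99), while fry called it lower with AP1510 (adjusted p = 0.048). Between treatments it had a camera adjusted p of 0.92 for TGF-alpha against AP1510, 0.48 for heregulin against AP1510, where fry called it higher (adjusted p = 0.049), and 0.66 for heregulin against TGF-alpha.

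AP1510 against untreated asks what HER2 homodimers change. HSD11B2, the enzyme that inactivates cortisol, rose most, by 6.07-fold (log2 change 2.60 ± 0.21, adjusted p = 3.6e-05). The transcription factor gene TFCP2L1 rose 2.95-fold, the mucin gene MUC21 2.43-fold, the calcium-binding protein gene S100A2 2.42-fold and the cathepsin gene CTSV 2.29-fold. SCNN1B, a subunit of the epithelial sodium channel, rose 2.09-fold and BMAL1, a core clock activator, rose 1.90-fold. TNFSF10, the death ligand TRAIL, fell most, by 2.63-fold (log2 change -1.40 ± 0.18, adjusted p = 7.7e-04). CLCA2 fell 2.47-fold, CD14, a co-receptor for bacterial lipopolysaccharide, 2.36-fold, and MYLK, myosin light chain kinase, 2.03-fold. In all, 271 of 18417 genes passed (1.47%), 142 higher and 129 lower, and 2038 had an unadjusted p under 0.05. Only 19 of the 271 genes that passed changed by at least 2-fold, 7 higher and 12 lower. The count was 95 without AP1510 replicate 1 and 117, 149 and 134 without untreated replicates 1, 2 and 3.

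Of 30 mitosis genes, 20 rose with AP1510, 0 fell and 10 did not pass, and 30 rose adjusted over the list alone (camera adjusted p = 3.5e-46, adjusted p = 0.064 with an estimated correlation). MKI67, the proliferation marker Ki-67, rose 1.76-fold (adjusted p = 4.8e-04), and the spindle checkpoint gene BUB1 rose 1.70-fold, the kinetochore motor gene CENPE 1.69-fold and the kinesin gene KIF20A 1.65-fold. The number of mitosis genes that rose was 6 without AP1510 replicate 1 and 12, 10 and 12 without untreated replicates 1, 2 and 3, while camera at the preset correlation called the list with each of the 12 arrays left out in turn. Among 30 replication genes, 1 rose and 29 did not pass, while 24 rose adjusted over the list alone (camera adjusted p = 4.6e-19, adjusted p = 0.066 with an estimated correlation). The member that passed was ORC1, at 1.47-fold, and it missed the threshold in 5 of the 12 refits that left out 1 array (adjusted p = 0.13 without AP1510 replicate 1). The number of replication genes that rose was 0 without untreated replicate 1, 2 or 3 or AP1510 replicate 1, 3 without heregulin replicate 1 and 2 without heregulin replicate 2. Cholesterol synthesis genes were shifted upward, with 4 of 18 risen and 7 adjusted over the list alone (camera adjusted p = 9.7e-09, adjusted p = 0.092 with an estimated correlation). Of these, ACAT2 rose 1.56-fold and SQLE, squalene epoxidase, 1.35-fold. Both missed the threshold without AP1510 replicate 1 (adjusted p = 0.06 and 0.17), and SQLE did so in 7 of the 12 refits. Without that array 0 cholesterol genes passed, with 1 risen without untreated replicate 1 or 2, AP1510 replicate 3 or TGF-alpha replicate 1, and 2 without untreated replicate 3, AP1510 replicate 2 or TGF-alpha replicate 2. Ribosome biogenesis genes had 0 of 21 passed, also 0 adjusted over the list alone, and a camera adjusted p of 0.03 (adjusted p = 0.55 with an estimated correlation). That call ended without AP1510 replicate 1 (adjusted p = 0.76) and without untreated replicate 2 (adjusted p = 0.05), and fry did not call the list (adjusted p = 0.4).

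Several lists shifted downward with AP1510, and in all of those given here except the immediate early genes most members did not pass. Among 17 immediate early genes, 9 fell and 8 did not pass, with 12 fallen adjusted over the list alone (camera adjusted p = 4.1e-15, adjusted p = 0.092 with an estimated correlation). The number fallen was 4 without AP1510 replicate 1 and also 4 without untreated replicate 1 or 2. EGR3 fell 2.22-fold (adjusted p = 0.0051) and FOS 1.69-fold (adjusted p = 0.0011), both genes of transcription factors. Of 20 ERK feedback and output genes, 2 fell, or 3 adjusted over the list alone (camera adjusted p = 1.3e-05, adjusted p = 0.18 with an estimated correlation). LIF, a cytokine of the IL-6 family, fell 2.25-fold. Only 1 ERK gene fell without untreated replicate 1 or 3, AP1510 replicate 1 or 2, TGF-alpha replicate 1, 2 or 3 or heregulin replicate 3. Inflammatory genes had 5 of 24 fallen, or 10 adjusted over the list alone (camera adjusted p = 1.3e-07, adjusted p = 0.066 with an estimated correlation), with IL6 down 2.03-fold, CXCL1 1.69-fold and SOD2 1.64-fold. The number fallen was 3 without untreated replicate 1, 2 or 3, AP1510 replicate 1, TGF-alpha replicate 2 or heregulin replicate 1 or 3. Interferon genes had 4 of 24 fallen, or 5 adjusted over the list alone (camera adjusted p = 0.012, adjusted p = 0.11 with an estimated correlation), with IFITM1 down 2.12-fold and CXCL10 1.74-fold. The interferon call ended with dim genes left out (adjusted p = 0.19), and 2 members fell without untreated replicate 1 or 2 or AP1510 replicate 1 or 2. FOXO targets had 3 of 15 fallen, or 1 risen and 5 fallen adjusted over the list alone (camera adjusted p = 4.5e-04, adjusted p = 0.064 with an estimated correlation). PDK4, an inhibitor of pyruvate oxidation, fell 1.79-fold and TXNIP 1.57-fold. Proteases and inhibitors had 1 risen and 3 fallen of 20, or 1 and 7 adjusted over the list alone (camera adjusted p = 5.5e-04, adjusted p = 0.11 with an estimated correlation). TIMP3, a metalloproteinase inhibitor, fell 1.80-fold. Without untreated replicate 1 or 3 or AP1510 replicate 1, only 1 of these genes fell, and 0 rose without untreated replicate 2 or 3 or AP1510 replicate 1 or 2. In the amino acid list, 1 of 20 fell, or 3 adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.18 with an estimated correlation). That member, HERPUD1, missed the threshold in 10 of the 12 refits that left out 1 array, and in those refits 0 fell. It kept its call only without heregulin replicate 1 or 2. The amino acid call ended without AP1510 replicate 3 (adjusted p = 0.064).

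Among members of the squamous and basal lists, KRT16 rose 1.90-fold (adjusted p = 6.1e-04), KRT10, of suprabasal keratinocytes, 1.89-fold, and KRT14, of basal cells, 1.40-fold with AP1510 (adjusted p = 0.0061), while most members of both lists did not pass. Squamous genes counted 3 risen and 2 fallen of 34, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0055, adjusted p = 0.14 with an estimated correlation). S100A8, a calprotectin subunit gene on that list, fell 2.11-fold. Basal markers had 2 of 9 risen, also 2 adjusted over the list alone (camera adjusted p = 0.035, adjusted p = 0.13 with an estimated correlation). The squamous call ended without untreated replicate 1 (adjusted p = 0.063), and the basal call without untreated replicate 3 (adjusted p = 0.077) and AP1510 replicate 3 (adjusted p = 0.075). Only 1 basal marker rose without untreated replicate 1 or 3 or AP1510 replicate 1. Leaving out 1 array ended the call of 20 of the 53 named genes that passed in this contrast, with adjusted p up to 0.2 and no change of sign.

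TGF-alpha against untreated asks what the EGFR ligand changes. It moved more genes than the other ligands: 4781 of 18417 passed (26%), 2311 higher and 2470 lower, and 750 of them by at least 2-fold. The ETS factor gene ETV1 rose most, by 8.64-fold (log2 change 3.11 ± 0.12, adjusted p = 1e-10). NT5E, an ectoenzyme that makes adenosine, rose 8.10-fold, ASNS, asparagine synthetase, 7.37-fold, the chemokine receptor gene CXCR4 6.39-fold and the cyclin gene CCNA1 6.34-fold. TNFSF10 fell most, by 15.9-fold (log2 change -3.99 ± 0.18, adjusted p = 4.3e-10). VTCN1, a T-cell inhibitory ligand, fell 14.6-fold, GBP2, an interferon-induced GTPase, 9.88-fold, and ID2, an inhibitor of bHLH factors, 6.37-fold.

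Mitosis, replication and ribosome biogenesis genes rose widely with TGF-alpha. All 30 mitosis genes rose (camera adjusted p = 1.5e-33, adjusted p = 0.066 with an estimated correlation), MKI67 by 3.64-fold and the mitotic kinase gene PLK1 by 3.42-fold. Of 30 replication genes 28 rose, or 29 adjusted over the list alone (camera adjusted p = 1.7e-27, adjusted p = 0.064 with an estimated correlation). TYMS, thymidylate synthase, rose 5.28-fold and CDC45, part of the replicative helicase, 4.19-fold. All 21 ribosome biogenesis genes rose (camera adjusted p = 2.7e-16, adjusted p = 0.072 with an estimated correlation), with CAD, of pyrimidine synthesis, up 2.55-fold and ODC1, of polyamine synthesis, 2.41-fold. Adjusted over the list alone, the mitosis and ribosome counts were again 30 and 21. The amino acid list had 10 risen and 4 fallen of 20, or 12 and 4 adjusted over the list alone (camera adjusted p = 2e-05, adjusted p = 0.066 with an estimated correlation). PSAT1 and PHGDH, both of serine synthesis, rose 6.84-fold and 5.31-fold, and SLC7A11, the cystine transporter, 3.64-fold, while 2 members fell without untreated replicate 2 or TGF-alpha replicate 1. Cholesterol genes had 12 risen and 1 fallen of 18, or 13 and 1 adjusted over the list alone (camera adjusted p = 6e-08, adjusted p = 0.1 with an estimated correlation), with ACAT2 up 3.37-fold and 0 fallen without untreated replicate 2 or 3 or TGF-alpha replicate 1 or 3. Fatty acid genes had 6 risen and 2 fallen of 12, the same counts adjusted over the list alone (camera adjusted p = 0.041, adjusted p = 0.28 with an estimated correlation), with ACLY, ATP citrate lyase, up 1.68-fold. Only 1 fatty acid gene fell without untreated replicate 1, 2 or 3, TGF-alpha replicate 1, 2 or 3 or heregulin replicate 3. That call ended without untreated replicate 2 (adjusted p = 0.079) and TGF-alpha replicate 2 (adjusted p = 0.064), after renewed quantile normalization (adjusted p = 0.067) and with dim genes left out (adjusted p = 0.076). Hypoxia genes had 7 risen and 2 fallen of 16, the same adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.25 with an estimated correlation), with BNIP3, of mitophagy, up 2.40-fold. Basal markers had 5 risen and 1 fallen of 9, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0043, adjusted p = 0.066 with an estimated correlation), with the integrin gene ITGA6 up 2.45-fold.

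Other lists shifted downward with TGF-alpha. Of 17 immediate early genes 15 fell, also 15 adjusted over the list alone (camera adjusted p = 1.3e-14, adjusted p = 0.097 with an estimated correlation), with CCN2, a matricellular protein gene, down 7.95-fold and FOSB 7.70-fold. ERK feedback and output genes split, with 10 risen, 8 fallen and 2 not passed, the same adjusted over the list alone, and the list did not pass with camera (adjusted p = 0.066), while fry called it higher (adjusted p = 6.5e-04). ETV5, an ETS factor gene on it, rose 6.57-fold. FOXO targets had 3 risen and 8 fallen of 15, or 3 and 9 adjusted over the list alone (camera adjusted p = 5.8e-04, adjusted p = 0.064 with an estimated correlation). FBXO32, a ubiquitin ligase subunit, fell 5.16-fold and BCL2L11, the pro-apoptotic BIM, 2.94-fold, and 1 target rose without TGF-alpha replicate 3. Inflammatory genes had 1 risen and 10 fallen of 24, the same adjusted over the list alone (camera adjusted p = 1.1e-04, adjusted p = 0.11 with an estimated correlation), and CXCL1, a neutrophil chemokine, fell 3.58-fold, with 2 risen without untreated replicate 2 or TGF-alpha replicate 1. Interferon genes had 1 risen and 10 fallen of 24, or 1 and 11 adjusted over the list alone (camera adjusted p = 1.5e-04, adjusted p = 0.064 with an estimated correlation), and IRF1 fell 4.84-fold, with 0 risen without untreated replicate 2 or 3, AP1510 replicate 2, TGF-alpha replicate 2 or 3 or heregulin replicate 3. Squamous genes had 4 risen and 14 fallen of 34, or 4 and 15 adjusted over the list alone (camera adjusted p = 0.0094, adjusted p = 0.16 with an estimated correlation), with S100A8 down 5.87-fold and the kallikrein gene KLK7 2.99-fold. Proteases and inhibitors had 1 risen and 10 fallen of 20, or 1 and 11 adjusted over the list alone (camera adjusted p = 0.0011, adjusted p = 0.12 with an estimated correlation), with the metalloproteinase gene MMP7 down 4.18-fold. Leaving out 1 array ended the call of 1 of the 81 named genes that passed in this contrast.

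Heregulin against untreated asks what the HER3 and HER4 ligand changes. RIPOR2 rose most, by 16.6-fold (log2 change 4.06 ± 0.34, adjusted p = 1e-06). Complement factor B (CFB) rose 15.3-fold (log2 change 3.94 ± 0.11, adjusted p = 5.3e-12), the serum amyloid genes SAA1 and SAA2 11.1-fold and 9.60-fold, the antichymotrypsin gene SERPINA3 8.42-fold and the complement protease gene C1S 7.28-fold. IL1R2, a decoy receptor for interleukin-1, rose 8.21-fold, and MAOA, monoamine oxidase A, 6.78-fold. TCN1, a vitamin B12 carrier, fell 6.96-fold (log2 change -2.80 ± 0.22, adjusted p = 7.2e-07). VTCN1 fell 6.69-fold, the imprinted gene PEG10 5.62-fold and TNFSF10 4.58-fold. In all, 1566 genes passed (8.50%), 635 higher and 931 lower, and 193 by at least 2-fold. The count was 1039 without untreated replicate 3.

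Several lists shifted upward with heregulin. Squamous genes had 11 risen and 6 fallen of 34, or 14 and 7 adjusted over the list alone (camera adjusted p = 6.5e-05, adjusted p = 0.066 with an estimated correlation). SERPINB3 rose 7.97-fold, KRT10 5.75-fold, the elastase inhibitor gene PI3 5.71-fold and S100A9 4.03-fold. Inflammatory genes had 8 risen and 2 fallen of 24, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.0026, adjusted p = 0.17 with an estimated correlation). SOD2, mitochondrial superoxide dismutase, rose 3.17-fold and CCL20, a chemokine, 2.02-fold. Ribosome biogenesis genes had 11 risen of 21, or 14 adjusted over the list alone (camera adjusted p = 1.5e-10, adjusted p = 0.12 with an estimated correlation), with NOLC1 up 1.57-fold. The number risen was 6 without untreated replicate 3 or heregulin replicate 1 and 5 without heregulin replicate 3. Mitosis genes had 12 risen of 30, or 15 adjusted over the list alone (camera adjusted p = 5.2e-10, adjusted p = 0.22 with an estimated correlation), with CDC20, an activator of mitotic exit, up (log2 change 0.58 ± 0.13) and MKI67 up 1.42-fold. The number risen was 5, 6 and 7 without untreated replicates 1, 2 and 3, 5 without heregulin replicate 1 and 2 without heregulin replicate 3. Cholesterol genes had 4 risen of 18, or 9 risen and 1 fallen adjusted over the list alone (camera adjusted p = 0.022, adjusted p = 0.43 with an estimated correlation), with SQLE up 1.70-fold. The number of them risen was 1 without untreated replicate 1 or 2 or heregulin replicate 1 or 3, and 2 without untreated replicate 3. In addition, 1 fell without AP1510 replicate 1 or heregulin replicate 3. Mesenchymal genes had 4 risen and 1 fallen of 24, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.03, adjusted p = 0.3 with an estimated correlation), with the proteoglycan gene DCN up 3.01-fold. Only 2 mesenchymal genes rose without untreated replicate 1, and 0 fell without untreated replicate 1 or 2 or heregulin replicate 3. Hypoxia genes had 4 risen and 2 fallen of 16, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.039, adjusted p = 0.35 with an estimated correlation), with CA12, a carbonic anhydrase, up 2.21-fold and 1 fallen without untreated replicate 2 or 3 or heregulin replicate 1 or 2. The cholesterol call ended without heregulin replicate 1 (adjusted p = 0.069) and replicate 3 (adjusted p = 0.13). The mesenchymal call ended without untreated replicate 1 (adjusted p = 0.1) and heregulin replicate 2 (adjusted p = 0.12), and with dim genes left out (adjusted p = 0.11). The hypoxia call ended without AP1510 replicate 3 (adjusted p = 0.055) and heregulin replicate 3 (adjusted p = 0.22).

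Other lists shifted downward with heregulin. ERK feedback and output genes had 1 risen and 12 fallen of 20, the same adjusted over the list alone (camera adjusted p = 4.8e-10, adjusted p = 0.092 with an estimated correlation). PHLDA1 fell 3.14-fold and the ERK phosphatase gene DUSP4 2.56-fold, with 0 risen without untreated replicate 1 or 3 or heregulin replicate 3. Immediate early genes had 11 fallen of 17, or 13 adjusted over the list alone (camera adjusted p = 3.4e-12, adjusted p = 0.12 with an estimated correlation), with EGR3 down 3.68-fold and JUN 2.41-fold. Proteases and inhibitors had 2 risen and 7 fallen of 20, or 2 and 8 adjusted over the list alone (camera adjusted p = 0.003, adjusted p = 0.15 with an estimated correlation), with the urokinase gene PLAU down 3.19-fold and MMP2 2.43-fold. Of the proteases, 0 rose without untreated replicate 1 or 3 or heregulin replicate 1, and 1 without heregulin replicate 3. Leaving out 1 array ended the call of 9 of the 65 named genes that passed in this contrast, with adjusted p up to 0.18.

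**Figure D2:**
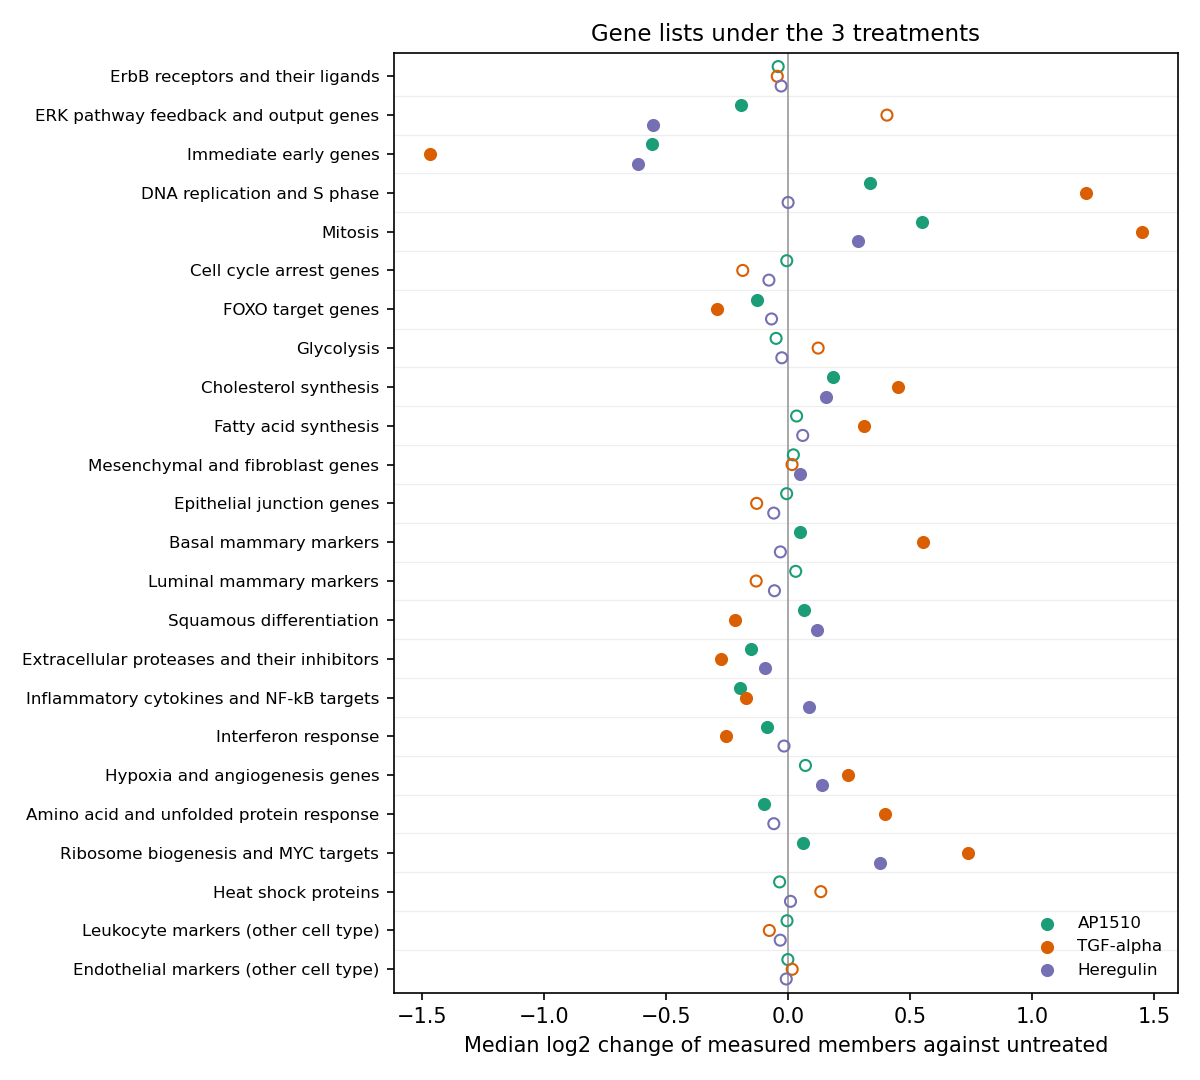
Median log2 change of the measured members of each of the 24 gene lists (vertical axis) against untreated (horizontal axis), 1 point per treatment. Filled points passed camera with the preset correlation and open points did not, and mitosis medians were 0.55 with AP1510, 1.45 with TGF-alpha and 0.29 with heregulin.

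Some genes stood apart in a single treatment by all 3 direct contrasts. In AP1510 cells 16 genes did, 11 higher and 5 lower. Their smallest differences reached 1.76-fold for ATP6V0D2, a proton pump subunit, and for the kallikrein gene KLK6, 1.68-fold for CRYAB, a small heat shock protein, and 1.65-fold for CA2, carbonic anhydrase 2. MT1X, a metallothionein gene, was lower by at least 1.48-fold. The rise of KLK6 over untreated missed the threshold in 7 of the 12 refits that left out 1 array (adjusted p = 0.17 without untreated replicate 1). The AP1510 count was 10, 7 and 7 without untreated replicates 1, 2 and 3 and 10 without TGF-alpha replicate 3. In TGF-alpha cells 2480 genes stood apart, 1380 higher and 1100 lower. The higher ones included ETV1 (8.63-fold), NT5E (8.10-fold), ASNS (7.37-fold) and PHGDH (5.31-fold), and the lower ones STEAP4 (6.57-fold), the selenium carrier SELENOP (5.12-fold) and MMP7 (4.18-fold). In heregulin cells 354 genes stood apart, 209 higher and 145 lower. CFB (15.3-fold), SAA2 (9.60-fold), C1S (7.28-fold) and the steroid enzyme gene HSD17B2 (5.64-fold) were higher, and PEG10 (3.90-fold), PHLDA1 (3.01-fold) and the adhesion gene EPCAM (2.13-fold) were lower.

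**Figure D3:**
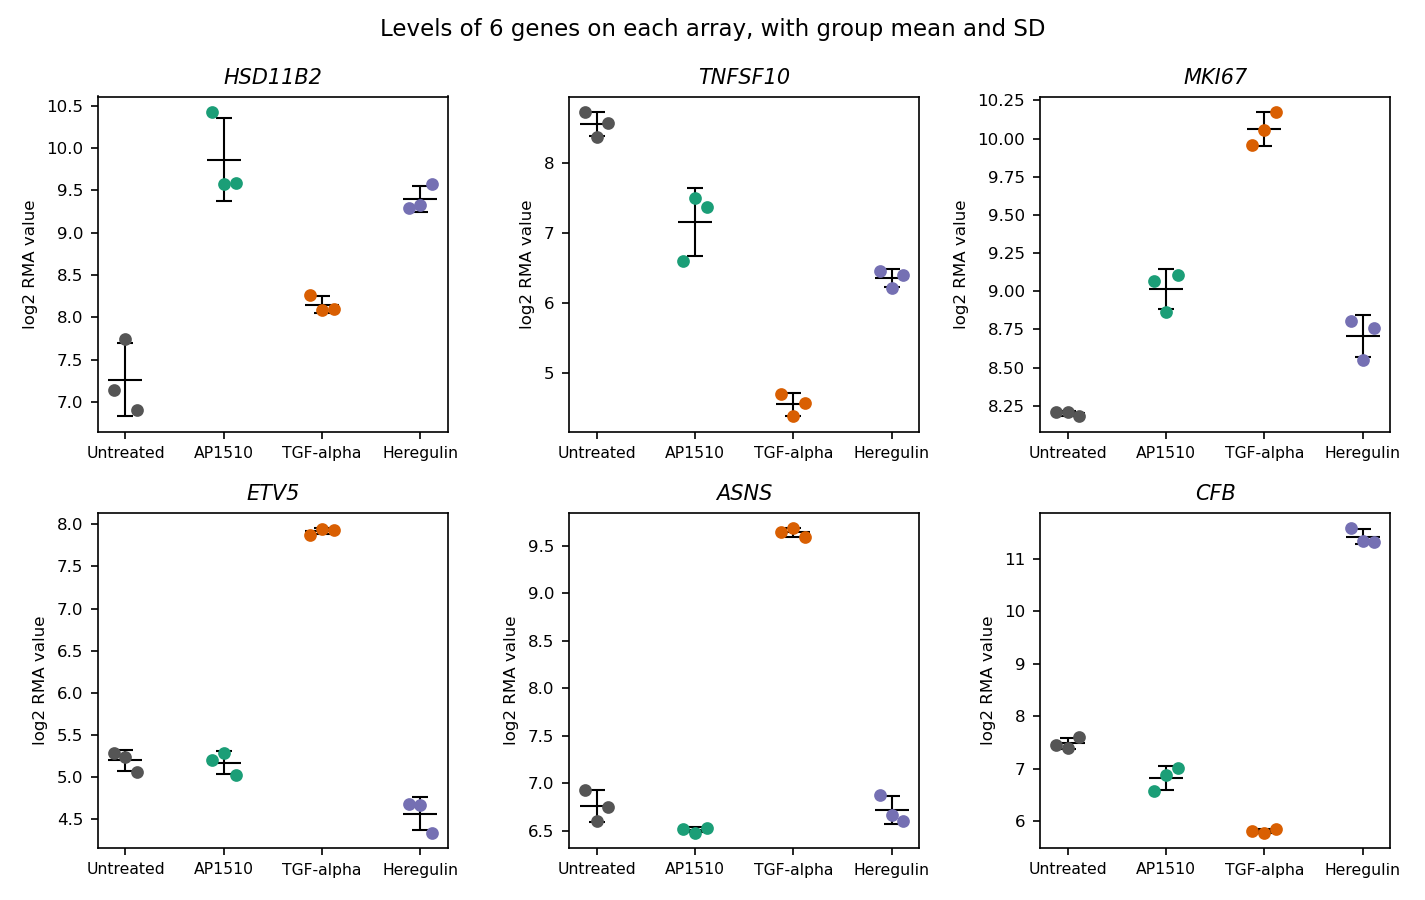
Log2 RMA values (vertical axes) of HSD11B2, TNFSF10, MKI67, ETV5, ASNS and CFB in the 4 groups, 1 point per array with group mean and SD. Mean TNFSF10 values were 8.55 in untreated, 7.15 in AP1510, 4.56 in TGF-alpha and 6.36 in heregulin cells.

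TGF-alpha against AP1510 compares EGFR ligand with HER2 homodimers directly. NT5E was 12.3-fold higher with TGF-alpha (log2 change 3.62 ± 0.13, adjusted p = 9.7e-11), ASNS 8.78-fold and the ERK phosphatase gene DUSP6 4.91-fold. AGR2, a luminal secretory gene, was 6.88-fold lower (log2 change -2.78 ± 0.18, adjusted p = 3.7e-08), as were MMP7 (6.57-fold) and TNFSF10 (6.05-fold). In all 3981 genes passed, 2061 higher and 1920 lower with TGF-alpha, 464 by at least 2-fold. All 30 mitosis genes were higher (camera adjusted p = 1.3e-24, adjusted p = 0.091 with an estimated correlation), as were 27 of 30 replication genes (camera adjusted p = 2.4e-23, adjusted p = 0.065 with an estimated correlation) and all 21 ribosome genes (camera adjusted p = 2.4e-17, adjusted p = 0.066 with an estimated correlation). The same numbers passed adjusted over the list alone. ERK feedback genes had 11 higher and 4 lower of 20, or 11 and 6 adjusted over the list alone (camera adjusted p = 4.1e-04, adjusted p = 0.26 with an estimated correlation). That call ended with dim genes left out (adjusted p = 0.11). Immediate early genes had 11 lower of 17, also 11 adjusted over the list alone (camera adjusted p = 3.7e-10, adjusted p = 0.15 with an estimated correlation).

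Heregulin against AP1510 compares HER3 and HER4 ligand with HER2 homodimers. CFB was 24.2-fold higher with heregulin (standard error 0.11 on the log2 scale, adjusted p = 4.8e-13), SAA2 9.61-fold and S100A9 8.04-fold. PEG10 was 7.53-fold lower (log2 change -2.91 ± 0.15, adjusted p = 3.7e-09), as were the kallikrein genes KLK5 (4.12-fold) and KLK7 (3.95-fold). In all 1331 genes passed, 603 higher and 728 lower, 137 by at least 2-fold. The count was 818 without AP1510 replicate 2 and 859 without AP1510 replicate 3. Inflammatory genes had 9 higher of 24, or 11 adjusted over the list alone (camera adjusted p = 7.3e-09, adjusted p = 0.064 with an estimated correlation), with SOD2 5.19-fold higher. Replication genes had 11 lower of 30, or 19 adjusted over the list alone (camera adjusted p = 5.7e-14, adjusted p = 0.092 with an estimated correlation), with CDC6 1.64-fold lower.

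Heregulin against TGF-alpha compares the natural ligands. CFB was 48.9-fold higher with heregulin (log2 change 5.61 ± 0.11, adjusted p = 2.2e-14), S100A8 16.7-fold and STEAP4 11.2-fold. NT5E was 20.3-fold lower (log2 change -4.34 ± 0.13, adjusted p = 3.1e-12), ETV5 10.2-fold and PHGDH 8.14-fold. In all 3986 genes passed, 1820 higher and 2166 lower, 539 by at least 2-fold. Replication genes had 29 lower of 30 and mitosis genes 30 of 30, the same adjusted over the list alone (camera adjusted p = 1.4e-32 and 6e-32, adjusted p = 0.064 and 0.066 with an estimated correlation). Inflammatory genes had 11 higher of 24, also 11 adjusted over the list alone (camera adjusted p = 1e-07, adjusted p = 0.066 with an estimated correlation), with the NF-kB subunit gene NFKB2 4.08-fold higher. Glycolysis genes had 5 lower of 17, or 2 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.012, adjusted p = 0.43 with an estimated correlation), with PFKP, a phosphofructokinase, 2.73-fold lower. That call ended after renewed quantile normalization (adjusted p = 0.067) and with dim genes left out (adjusted p = 0.068).

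Several lists passed camera in no contrast against untreated. Cell cycle arrest genes had camera adjusted p of 0.92 with AP1510, 0.28 with TGF-alpha and 0.092 with heregulin, in that order of treatments. Glycolysis had 0.66, 0.078 and 0.72, epithelial junctions 0.54, 0.38 and 0.8, luminal markers 0.8, 0.064 and 0.19, and heat shock proteins 0.89, 0.16 and 0.74. Leukocyte markers had 0.9, 0.13 and 0.83, and endothelial markers 0.97, 0.99 and 0.87. By fry, which does not compare a list with other genes, 4 of these lists were called lower with TGF-alpha and 2 higher, although in 5 of the 6 members moved both ways. Lower were cell cycle arrest genes (2 risen and 5 fallen of 15, fry adjusted p = 0.0085), epithelial junctions (5 and 7 of 19, 0.032), luminal markers (4 and 9 of 20, 1.3e-04) and leukocyte markers (0 and 2 of 12, 1.2e-04). Higher were glycolysis (5 and 2 of 17, 0.0044) and heat shock proteins (5 and 3 of 13, 0.032). With heregulin, fry called cell cycle arrest genes (0 and 3 of 15, 0.027) and luminal markers (2 and 4 of 20, 0.024) lower. Several of these counts moved when 1 array was left out. With TGF-alpha, 1 arrest gene rose without untreated replicate 1, 2 or 3, AP1510 replicate 1, TGF-alpha replicate 1 or 3 or heregulin replicate 3, and 3 fell without untreated replicate 2 or 3 or TGF-alpha replicate 1 or 3. For junctions, 3 rose without untreated replicate 1 or TGF-alpha replicate 2. In glycolysis 1 fell without TGF-alpha replicate 1 or 3, and 1 heat shock gene fell without TGF-alpha replicate 1. With heregulin, 1 arrest gene fell without untreated replicate 1 or 3 or heregulin replicate 1 or 2. Of the 12 leukocyte markers, 1 fell with AP1510, 2 fell with TGF-alpha, and 1 rose and 1 fell with heregulin, with the same numbers fallen and 1, 0 and 1 risen adjusted over the list alone. Median, mean and test differed in sign for epithelial junctions with AP1510, for the ErbB, FOXO, fatty acid, basal and endothelial lists with heregulin, and for the ErbB and endothelial lists between TGF-alpha and AP1510. They also differed for the glycolysis, basal, leukocyte and endothelial lists between heregulin and AP1510 and for the endothelial list between heregulin and TGF-alpha. Camera called none of these, and fry called the basal list higher with heregulin (adjusted p = 0.0044).

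The responses were compared across genes, which are not independent replicates. Log2 changes of AP1510 and TGF-alpha correlated at 0.553, against 0.501 on average and 0.521 at most in simulations of unchanged groups set against the same controls. The value was 0.407, below the simulated mean, without AP1510 replicate 1. AP1510 and heregulin correlated at 0.404 (simulated 0.499), and TGF-alpha and heregulin at 0.469 (simulated 0.5). Simulated groups held no changes, so the simulated correlation is no lower limit for groups that changed. Correlations below it do not show unlike responses. Covariances were 0.0381, 0.0178 and 0.0521 for these pairs, beside 0.00635, 0.00634 and 0.00634 simulated. AP1510 and TGF-alpha shared 122 risen genes where 17.8 were expected from the counts alone, and 108 fallen genes where 17.3 were expected, while 11 moved in opposite directions. AP1510 and heregulin shared 58 risen (4.90 expected) and 74 fallen (6.52 expected), with 13 opposite. TGF-alpha and heregulin shared 351 risen (79.7 expected) and 646 fallen (125 expected), with 117 opposite. In the simulations of unchanged groups, at most 1 gene was called in both contrasts of a pair. With no changed gene few calls are made at all, so this value is no measure for the overlaps above. All comparisons use the same 3 untreated arrays, which were not divided between contrasts, so part of each excess may come from the shared controls. Of the 271 AP1510 genes, 230 passed in the same direction with TGF-alpha, 203 moved farther there, and 199 differed directly between the treatments. With heregulin, 132 passed in the same direction and 13 in the opposite one, 78 moved farther, and 106 differed directly. Without AP1510 replicate 1, 95 genes passed with AP1510 instead of 271, and the shared genes were not recounted.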

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

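Lists, named-gene rule, main tests and most alternatives were chosen before the data were examined. In this part, the tests of a weaker TGF-alpha response, of a single heregulin dish and of leukocytes were chosen only after the result was seen. The tests of carry-over and signal range concern a position of AP1510 replicate 1 that was itself found in these data. The test of a single dish was at first run on the list members that rose, which fixes its outcome, and was then replaced by a test on all measured members. Its outcome stayed partly fixed, because the list was made around genes already seen to rise. The 95% intervals and bounds in this part come from resampling genes with the arrays held fixed. Genes are not independent replicates, so these intervals leave out the spread between dishes.

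Probe sets that name no gene were not part of the comparisons, and some carried a signal that differed from untreated. Outside the numbering range of the inferred controls, 169 of 7880 rose and 130 fell with TGF-alpha, and 28 rose and 21 fell with heregulin. Within that range, 24 of 4203 rose and 7 fell with TGF-alpha, and 2 rose and 1 fell with heregulin. With AP1510, limma called 0 in either range. No transcript is assigned to them here.

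AP1510 replicate 1 lay nearer the TGF-alpha arrays, at 34.5% of the distance from untreated to TGF-alpha against 17.6% and 13.8% for replicates 2 and 3. RNA carried over from TGF-alpha cells would add the same share to every gene. Shares were computed only for list genes at least 2-fold higher with TGF-alpha than in AP1510 replicates 2 and 3. Of these, ERK and amino acid genes needed a median share of 1.21% (95% interval 0.15 to 5.09, 13 genes) and cell cycle genes 13.9% (9.4 to 17.9, 30 genes). Single genes overlapped, at -2.93% to 14.3% and -1.78% to 41.3%. The difference of the medians argues against carry-over as the whole cause. A stretched signal range would follow gene level, and the deviation correlated with level at 0.033 across genes. RMA had already equalised the distributions of the arrays, so this value does not decide on that cause. A dish that had cycled more is another possibility, and no biological explanation was tested, since the labels describe the 3 dishes alike.

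The mitosis and replication lists shifted upward with both AP1510 and TGF-alpha, so AP1510 may act as a weaker TGF-alpha. With AP1510, 20 of 30 mitosis genes but only 1 of 30 replication genes passed. Neither list passed camera with an estimated correlation under either treatment. A single lower strength would give like slopes of AP1510 on TGF-alpha changes in all groups. The slope was 0.0248 (95% interval -0.0342 to 0.116) over 40 ERK and amino acid genes and 0.32 (0.288 to 0.352) over 60 cell cycle genes. Without AP1510 replicate 1, chosen as an alternative after seeing the data, it was -0.00176 (-0.0489 to 0.0652) and 0.269 (0.236 to 0.301). This argues against a uniformly weaker response at 48 hours, while different timing or a threshold for some genes was not tested and stays open.

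Of 12 acute phase and complement genes, a list made after CFB and SAA1 had been seen, 8 rose with heregulin and 4 did not pass (camera adjusted p = 7.1e-23, adjusted p = 0.0042 with an estimated correlation). These p-values were adjusted only among the lists chosen after values were seen. Over all 12, the median log2 change was 1.67, 1.5 and 1.39 in heregulin replicates 1, 2 and 3, so the median rose on each array. The lower 95% bound of the second highest, 0.414, lay above the highest upper bound of an untreated array, 0.216. CFB and SAA1, which prompted the list, were named by a rule that needs all 3 heregulin arrays on one side of the untreated ones. The outcome was thus partly fixed in advance, and this test does not decide on a single dish. Leukocytes would raise their abundant transcripts, but the median change of 12 markers was -0.032 (95% interval -0.092 to 0.046), and LYZ and PTPRC stood at 2.89 and 2.92 with heregulin and 2.98 and 3.01 untreated. Of these markers, CD14 (9.61 untreated) and CD68 (7.91) were well above the lowest levels in these epithelial cells, and CSF1R rose while CD14 fell. A response of the epithelial cells may remain, as a hypothesis found and tested on the same data.

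Other splits of the arrays were counted. With 6 arrays there are 10 splits, too few for a share under 0.05, and 1 of 10, the real one, gave as many genes in each contrast. The real counts were 271, 4781, 1566, 3981, 1331 and 3986, and the highest other was 0 in each. Every other split puts arrays of both groups on each side, which moves a real difference into the spread. Low counts in them are thus built in wherever the groups differ. List p-values in these splits were adjusted within each contrast, not over the 144 tests together. The list counts may therefore differ from the calls given above. The contrasts follow in the order AP1510, TGF-alpha and heregulin against untreated, TGF-alpha and heregulin against AP1510, and heregulin against TGF-alpha. In that order, the real list counts were 13, 14, 10, 17, 7 and 13. The highest others were 9, 10, 6, 10, 7 and 10, although 0 genes passed in any other split. Camera at the preset correlation can thus call lists where no single gene passes. How many such calls chance would give was not tested. In the contrast of heregulin with AP1510, 2 of 10 splits gave as many lists. Among 100 splits of all 12 arrays, the real one gave the most genes differing among groups (5248, highest other 3453). It also gave the most genes apart in TGF-alpha (2480, highest other 2140) and in AP1510 (16, highest other 1). A count of 354 or more genes apart in heregulin was reached by 3 of 100, the real one included (highest other 2247). These splits do not decide whether chance explains any of these counts. Those of all 12 arrays mix TGF-alpha arrays into other groups, which raised the median SD from 0.128 to between 0.136 and 0.164 and leaves few small differences to be called. The 2 other splits that reached 354 gave several times the real count and point to a structure, since both put all 3 TGF-alpha arrays in that group.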

How the results depend on the processing

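The alternatives reversed the sign of no named gene that passed and of no correlation of responses, but the balance of risen and fallen genes changed sides. Against 2311 risen and 2470 fallen, TGF-alpha gave 2353 and 2212 with equal medians and 2156 and 2086 without TGF-alpha replicate 1. Against 2061 and 1920, TGF-alpha against AP1510 gave 1997 and 2059 after renewed quantile normalization and 1655 and 1676 without TGF-alpha replicate 2. Against 142 and 129, AP1510 gave 71 and 78 without untreated replicate 2 and 125 and 160 without AP1510 replicate 3. Against 603 and 728, heregulin against AP1510 gave 433 and 426 without AP1510 replicate 3 and 522 and 452 without heregulin replicate 2. Against 1820 and 2166, heregulin against TGF-alpha gave 1852 and 1822 without heregulin replicate 2. Renewed quantile normalization, equal medians, the mean of probe sets and removal of dim genes left every count within 1.5 times. Causes of the changes were not tested, though a stricter threshold lowers a count by construction. Fewer arrays did not always lower it, since AP1510 against untreated gave 327 genes without heregulin replicate 2, beside 271 with all arrays. A trended robust prior gave 28 genes apart in AP1510. Array weights, which gave heregulin replicate 3 a weight of 4.62 and replicate 2 a weight of 0.322, gave 3000 genes for heregulin against untreated, 2452 for heregulin against AP1510, 28 apart in AP1510 and 690 apart in heregulin. Each contrast on its own 6 arrays gave 743 for heregulin against AP1510 and 7 apart in AP1510. All probe sets gave 177 for AP1510 against untreated and 9 apart in AP1510. A 2-fold minimum gave 19, 750 and 193 for AP1510, TGF-alpha and heregulin against untreated, 464 and 137 for TGF-alpha and heregulin against AP1510, 539 for heregulin against TGF-alpha, 959 among the 4 groups, and 0, 276 and 42 apart in AP1510, TGF-alpha and heregulin. An adjusted p of 0.01 gave 85 for AP1510 and 829 for heregulin against untreated, 650 for heregulin against AP1510, and 2 and 207 apart in AP1510 and heregulin. No moderation gave 50 for AP1510 against untreated, 843 for heregulin against AP1510 and 2 apart in AP1510.

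Leaving out each array in turn gave 95 to 327 genes for AP1510 against untreated, 1039 to 1602 for heregulin against untreated, 818 to 1323 for heregulin against AP1510 and 7 to 15 apart in AP1510. The correlation of AP1510 and TGF-alpha changes ran from 0.407 to 0.579, and no simulation was made with an array left out. All 72 called lists lost their call with an estimated correlation. Removal of dim genes ended 9 list calls, renewed quantile normalization 3 and fry 1. Equal medians moved the share of genes that rose most for heregulin against TGF-alpha, from 45.7% to 36.7%. No paired analysis was possible because array numbers in the labels run on from group to group and pair no dishes. With 3 arrays per group, their number limits the precision.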

Other observations

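All tests in this part were chosen only after the result was seen. List p-values here were adjusted only among such later lists, so they do not compare with those of the planned lists. Genes that glucocorticoids induce rose with both natural ligands in medium that still held hydrocortisone. Of 12, 10 rose with heregulin (adjusted p = 0.0096 with an estimated correlation), 10 rose and 1 fell with TGF-alpha (adjusted p = 0.12 with an estimated correlation), and 1 rose with AP1510 (adjusted p = 0.16 with an estimated correlation). ZBTB16, a transcription factor gene, rose 6.24-fold with heregulin and 3.30-fold with TGF-alpha. The member that rose with AP1510 was TFCP2L1. GLUL, glutamine synthetase, fell 2.15-fold with TGF-alpha. Of 8 metallothionein genes, 7 rose with heregulin (adjusted p = 0.0042 with an estimated correlation) and 7 with TGF-alpha (adjusted p = 0.017 with an estimated correlation), while 1, MT1X, fell with AP1510. MT2A rose 3.64-fold with heregulin and 4.71-fold with TGF-alpha. Of the 3 sodium channel subunits, SCNN1B rose with every ligand, SCNN1G rose 6.92-fold with TGF-alpha and 6.56-fold with heregulin, and SCNN1A rose with heregulin (log2 change 0.58).

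Replication-dependent histone genes separated the ligands. Of 58, 41 rose and 1 fell with TGF-alpha (adjusted p = 0.0096 with an estimated correlation), 5 rose with AP1510 (adjusted p = 0.034 with an estimated correlation) and 4 fell with heregulin (adjusted p = 0.24 with an estimated correlation). H1-5, a linker histone gene, rose 4.29-fold with TGF-alpha and 1.57-fold with AP1510. Heregulin against TGF-alpha gave 43 lower and 1 higher (adjusted p = 0.0066 with an estimated correlation).

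Of 15 clock genes, 2 of 5 on a first list rose and 3 of 10 on another fell with AP1510, and 10 did not pass. BMAL1 rose 1.90-fold, CRY1 rose 1.63-fold, and NR1D2 and NR1D1, which repress BMAL1, fell 1.95-fold and 1.73-fold. A hypothesis was that the clock's arms moved in opposite directions. With BMAL1, CLOCK, NPAS2, CRY1 and NFIL3 set against 10 repressor and output genes, the mean difference was 0.775 on the log2 scale, with an exact two-sided permutation p of 0.000333, the smallest that 3003 regroupings can give (adjusted p = 0.002 over 6 contrasts). The same grouping gave 1.33 with TGF-alpha (adjusted p = 0.011) and 1.01 with heregulin (adjusted p = 0.0652). CRY1 and NFIL3 are repressors, however, and were placed with the activators after their values were seen. With both moved to the other genes, the difference was 0.604 and the exact permutation p was 0.0527 (adjusted p = 0.18), and it was 1.03 with TGF-alpha (adjusted p = 0.18) and 0.409 with heregulin (adjusted p = 0.614), so no contrast against untreated passed. The harvest time of the untreated cells, on which clock genes depend, is not given in the sources used here. The hypothesis may hold, but it rests on that placement and cannot be told apart from a chance choice of genes.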
